A study of Homo sapiens with 192 samples.

How the data were processed

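HUES-9 human embryonic stem cells, either untreated or treated with BMP4 and collected after day 2, were captured singly on a Fluidigm C1 chip, a microfluidic device with 96 wells. cDNA was made with the SMARTer kit and libraries with Nextera XT, and they were sequenced on an Illumina HiSeq, per the labels' protocols. Wells with debris or with 2 or more cells were excluded by the submitters, per the same protocols, so no doublet caller was run. The deposited values are RPKM, reads per kilobase of gene model per 1000000 reads, in 1 column per cell, made by the authors; the unit was taken from how the tables are named, and values were neither whole nor summed to a common total. The genome build was hg19, per the submitters' processing notes. The aligner, the counter, the annotation and the gene filter are not given in the sources used here. The tables hold 20337 genes, each above an RPKM of 1 in at least 3 cells over both groups.

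Groups were taken from the labels: 96 cells each, of which 86 BMP4 and 79 untreated cells have a column. The labels name no culture and number no chip; the 96 cells of a group equal the wells of 1 chip, from which 1 chip per group was inferred, and each group has its own sequencing run, so a group counts as 1 sample, run or chip and group cannot be told apart, and cells are not replicates. No test of BMP4 against untreated cells was run, and no p-value, standard error or number of changed genes is given. Intervals on shares are exact binomial 95% intervals and, like the limits for 0 cells (3 cells of the total), cover counting error only. Cells needed at least 2000 genes at an RPKM of 1 or more, which removed 1 untreated cell. No result names XIST or a Y-linked gene, and XIST was left out of the X-linked comparison. Values over all genes, the random lists and the clustering did not leave them out. Symbols are those of the deposited tables. Of these, 15415 (75.8%) matched a RefSeq symbol or synonym that gave the chromosome of the gene. GENCODE release 29, which is on another genome build, was used only for pseudogenes and for the lengths that set the depth scale. No coordinates are given. AMER2 also has a second row under an older symbol.

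Depth was estimated from the RPKM themselves, since a gene's low values are whole multiples of what 1 read is worth: of 343411 low values in 17910 genes with such a step, 99.9991% were whole within 0.1. Reads per cell are relative to a scale set by gene lengths: only 28.4% of 12725 genes lay within 5% of the most common ratio of step to annotated length, so the absolute depth is an estimate. Cells were thinned to 1000000 of these reads, over the genes with such a step only, to compare numbers of genes and shares of cells. This was chosen after the data were seen.

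Per gene, the mean RPKM over cells was taken in each group, with the log2 ratio of (mean BMP4 + 1) to (mean untreated + 1). The pseudocount of 1 understates the ratio of low genes, and where a group was listed at 0 no ratio is given. Genes with a mean of 1 RPKM or more in either group counted as measured. The 28 gene lists were written before the data were examined; the mitochondrially encoded list had no gene in the tables, leaving 27. For each, members at least 2-fold higher or lower were counted by size, and the median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins. These percentiles describe these libraries only. Beside the splits of higher and lower members, the splits after rescaling each cell to 1000000 RPKM ("rescaling") and with median-of-ratios size factors ("size factors") are given where the share of higher members moved by over 10 percentage points; rescaling also raises values, so more members pass the minimum of 1.

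Genes named in the text followed a rule fixed beforehand: among genes with a mean of 10 RPKM or more in a group whose 25th to 75th percentile ranges over cells did not overlap, the 12 largest and 12 smallest log2 ratios, then in each list the 2 measured members at either end, and always POU5F1, NANOG, SOX2, CDX2, GATA3, ID1 and ID3. Antisense, mitochondrial and unnamed genes were skipped in the first part, and the filter for unnamed genes was corrected to the fixed rule without changing the named genes. Not every list member that the rule gave is printed. Other members of the lists are named as examples chosen after their values were seen. X-linked genes with a mean of 5 RPKM or more were compared with autosomal genes matched on expression; 82.3% of such genes had a chromosome. At a minimum of 1 RPKM the share was 79.1%, under the 80% set as a minimum, so that comparison is given as a value only. Cells were clustered by Ward's method on the first 10 principal components of log2(RPKM + 1) over the 1000 most variable genes, with 4 clusters.

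The steps were tested on simulated data. For the comparison of BMP4 with untreated cells, both simulated groups were drawn from untreated cells. Genes at 10 RPKM or more, changed by a known log2 of 1, 2, -1 and -2 (50 each), came out with medians of 0.93, 1.91, -0.93 and -1.81. Lower genes were not tested. Of 200 lists without signal, 3.50% lay outside the middle 95% of random lists. These lists were themselves drawn at random, so a low share follows by construction. It does not cover lists of genes that vary together or a difference between chips. Simulated low read numbers were recovered in 100% of values, with a step found for 98.2% of genes. In the clustering, 2 planted groups differing 4-fold were not recovered (54 cells misplaced), and groups differing 16-fold were (0 misplaced). An earlier simulation that resampled whole cells recovered neither and was replaced by one drawing each gene independently, so small clusters are described by size only. Alternatives covered the pseudocount, the cell filter, scaling, the summary over cells, 2 sets of wells, detection thresholds, expression minimums and cluster settings. Thinned shares, lists without shared members, X-linked genes without SAT1 and further gene pairs and shares with and without another gene were added after the data were seen. A test of depth as the cause of fewer genes per BMP4 cell was set aside after the thinned numbers had been seen, and those numbers are given as values. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9.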

Results

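Single HUES-9 cells, a human embryonic stem cell line, were profiled by RNA sequencing after treatment with BMP4, a growth factor of the TGF-beta family, and collection after day 2, or without treatment. Each group counted as 1 sample: its 96 labelled cells were taken as 1 capture chip, which has 96 wells, though the labels number no chip, and the sequencing run coincided with the group, so no difference between groups has a replicate check and no p-value is given. The labels listed 96 cells per group, of which 86 BMP4 cells and 79 untreated cells had RPKM values, and 78 untreated cells passed the minimum of 2000 genes at an RPKM of 1 or more. The excluded untreated cell had 1638 such genes.

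BMP4 cells had a median of 6776 genes at an RPKM of 1 or more (25th to 75th percentile 6159.5 to 7550.2), and untreated cells had 7714 (7331 to 8199). The median depth estimated from the size of 1 read was 2382580 reads per BMP4 cell and 2548250 per untreated cell. Thinning every cell to 1000000 reads left out 3 BMP4 and 6 untreated cells of all those with values. It used only the 17910 genes for which the size of 1 read was resolved. Of these genes, a median of 6829 had a read in BMP4 cells and 7744 in untreated cells (unthinned, 7327 and 8393). Over all genes, the medians above an RPKM of 0 were 8116 and 9182.5 in the cells passing the filter. The RPKM over all genes summed to a median of 341131 in BMP4 cells and 433484 in untreated cells. Over the 15064 genes with a mean RPKM of 1 or more in either group, the median log2 ratio of BMP4 to untreated cells was -0.31. It was -0.00301 after each cell was rescaled to the same RPKM sum and 0.11 with median-of-ratios size factors. Gene lists are therefore described by the percentile of their median among 10000 random lists of the same size and expression, which carry the same shift.

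The comparison of BMP4-treated with untreated cells asked which genes differed after the treatment. HPGD, which encodes the enzyme that inactivates prostaglandins, had the largest log2 ratio among the genes whose middle ranges over cells did not overlap, at 521 against 0.575 RPKM (log2 ratio 8.37). Its 25th to 75th percentile over cells was 214 to 689.6 RPKM in BMP4 cells, and it was detected in 98.8% of them (95% interval 93.7 to 99.97%) and in 3.85% of untreated cells (0.800 to 10.8%). The matrix glycoprotein gene FN1 (1345 against 8.78 RPKM), the granzyme inhibitor gene SERPINB9 (1464 against 21.4 RPKM) and the tight junction gene CLDN10 (2612 against 60.8 RPKM) were also among the 12 highest. The transcription factor genes GATA3 (61.4 RPKM) and TFAP2A (56.8 RPKM) were listed at 0 in every untreated cell, and TFAP2C was at 270.1 against 7.48 RPKM. The other members of the 12 were the transporter gene ABCG2 (58.1 against 0.149 RPKM, log2 ratio 5.69), RHOBTB3 (76.01 against 0.716 RPKM, log2 ratio 5.49), BMP4 (79.2 against 0.922 RPKM, log2 ratio 5.38), the ephrin gene EFNA1 (58.2 against 0.485 RPKM, log2 ratio 5.32) and AMER2 (36.4 against 0.00565 RPKM, log2 ratio 5.22).

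The gene with the smallest log2 ratio was the long noncoding RNA LINC00458, at 23.9 against 1265 RPKM (log2 ratio -5.67), with 25th to 75th percentiles of 0 to 20.3 and 804 to 1716 RPKM over cells. The homeobox gene HESX1 (0.569 against 48.5 RPKM), the zinc finger gene ZIC2 (10.7 against 229.7 RPKM) and TDGF1, which encodes a co-receptor for Nodal (27.7 against 489.8 RPKM), were among the 12 lowest. So were the metallothionein genes MT1X (10.7 against 255 RPKM, log2 ratio -4.46) and MT1G (3.04 against 53.8 RPKM, log2 ratio -3.76), the kinase genes PIM2 (1.80 against 57.1 RPKM, log2 ratio -4.37) and LCK (0.379 against 18.5 RPKM, log2 ratio -3.82), the secreted Wnt modulator gene SFRP2 (4.05 against 81.1 RPKM, log2 ratio -4.02), the deubiquitinase gene USP44 (4.35 against 76.7 RPKM, log2 ratio -3.86), PIPOX (0.277 against 19.5 RPKM, log2 ratio -4.002) and SHISA2 (6.83 against 106.8 RPKM, log2 ratio -3.78). Metallothionein genes are near-identical copies of each other, so how reads were divided among them is uncertain.

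Of 31 measured pluripotency regulators and markers, 22 were at least 2-fold lower in BMP4 cells, 0 at least 2-fold higher and 9 within 2-fold, with a median log2 ratio of -2.02 (percentile 0 of random lists; -1.22 with a pseudocount of 5). NANOG, a core pluripotency factor, was at 2.35 against 29.5 RPKM and was detected in 29.1% of BMP4 cells (95% interval 19.8 to 39.9%) and 100% of untreated cells (95.4 to 100%). SOX2 was at 1.32 against 7.42 RPKM and in 30.2% against 83.3% of cells, and the de novo methyltransferase gene DNMT3B was at 26.04 against 201 RPKM. POU5F1, the third of these core factors, differed less, at 5.88 against 12.3 RPKM (log2 ratio -0.96), with overlapping 25th to 75th percentiles of 1.85 to 7.25 and 7.05 to 16.5 RPKM. It was detected in 86.05% of BMP4 cells (76.9 to 92.6%) and 97.4% of untreated cells (91.04 to 99.7%). The RNA-binding protein genes LIN28A (49.2 against 63.2 RPKM) and LIN28B (12.2 against 10.5 RPKM) and the surface marker genes CD24 (429.7 against 334 RPKM) and PODXL (58.1 against 42.3 RPKM) lay within 2-fold. POU5F1 has 6 annotated pseudogenes, so its level is uncertain. At 1000000 reads per cell, POU5F1 had a read in 93.98% of BMP4 and 98.6% of untreated cells, and NANOG in 37.3% and 100%.

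Genes of Nodal, FGF and Lefty signalling, which maintains human pluripotent cells, were mostly lower in BMP4 cells: 11 of 19 measured members were at least 2-fold lower and 2 at least 2-fold higher, with a median of -1.25 (percentile 0; -2.10 at a minimum of 10 RPKM, with 6 lower). The FGF pathway feedback genes DUSP6 (23.6 against 223 RPKM) and SPRY1 (0.770 against 14.5 RPKM) were lower. LEFTY1 and NODAL were listed at 0 in all BMP4 cells and averaged 7.26 and 1.52 RPKM in untreated cells. The receptor genes FGFR3 (3.31 against 0.428 RPKM) and ACVR2B (13.7 against 4.77 RPKM) were the members at least 2-fold higher.

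BMP target genes were higher in BMP4 cells. Of 17 measured members, 13 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 2.18 (percentile 100; 1.46 to 4.35 over the alternatives). The inhibitor of DNA binding genes ID2 (373 against 12.6 RPKM), ID4 (23.2 against 1.04 RPKM) and ID1 (58.5 against 5.28 RPKM) were higher, and ID3 was at 213 against 126.99 RPKM (log2 ratio 0.74). ID1 was detected in 100% of BMP4 cells (95.8 to 100%) and 53.8% of untreated cells (42.2 to 65.2%). The homeobox genes DLX5 (31.99 RPKM) and MSX2 (19.7 RPKM) were listed at 0 in untreated cells, while the BMP antagonist gene NOG was at 17.5 against 0.200 RPKM. The smallest log2 ratios of the list were those of ID3 and of HEY1 (1.596 against 0.611 RPKM, log2 ratio 0.69).

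Of 33 measured early trophoblast regulators and epithelial genes, 23 were at least 2-fold higher in BMP4 cells and 2 at least 2-fold lower, with a median log2 ratio of 2.45 (percentile 100; 1.56 to 4.13 over the alternatives). GATA3 was detected in 98.8% of BMP4 cells (95% interval 93.7 to 99.97%) and in 0 of 78 untreated cells, which allows a share of up to 3.85%. TFAP2A (97.7% of BMP4 cells), HAND1 (69.8%) and VGLL1 (33.7%), all transcriptional regulators, were likewise detected in 0 of 78 untreated cells. The keratin genes KRT7 (34.5 against 0.196 RPKM), KRT19 (189.6 against 19.9 RPKM) and KRT8 (183.2 against 52.3 RPKM) were higher. CDX2, a trophectoderm regulator, was detected in 12.8% of BMP4 cells (6.56 to 21.7%) at a mean of 1.38 RPKM and was listed at 0 in untreated cells. The members with the lowest log2 ratios were TEAD4 (3.003 against 9.39 RPKM) and the laminin gene LAMA5 (11.7 against 33.3 RPKM).

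Of 31 genes of syncytiotrophoblast and extravillous trophoblast, only 13 had deposited values and 6 were measured. The gene filter is not given, so a gene without values cannot be called low. Of the 6, 2 were at least 2-fold higher and 1 at least 2-fold lower (median -0.31, percentile 40.8). These were the transcription factor gene TBX3 (15.02 against 0.00189 RPKM), CYP11A1, which encodes the first enzyme of steroid synthesis (5.46 against 0.407 RPKM), and the proteoglycan gene SDC1 (2.87 against 10.8 RPKM), respectively. Their counts were 4 and 1 after rescaling and 3 and 1 with size factors, and the median was 0.57 with size factors.

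Amnion genes were higher in BMP4 cells, with 10 of 13 measured members at least 2-fold higher, 1 at least 2-fold lower and a median of 2.68 (percentile 100; 1.51 to 3.61 over the alternatives). The LIM homeobox gene ISL1 was at 45.5 against 0.0297 RPKM and was detected in 66.3% of BMP4 cells (95% interval 55.3 to 76.1%) and 1.28% of untreated cells. GABRP, which encodes a GABA receptor subunit (18.8 against 0.113 RPKM), was in 38.4% of BMP4 cells, and the cathepsin gene CTSV (691 against 68.6 RPKM) in 100% of BMP4 and 97.4% of untreated cells. The lowest member was the tenascin gene TNC (0.431 against 3.31 RPKM). In the plot of single-cell values, GATA3, TFAP2A, KRT7, HAND1 and ISL1 have higher medians in BMP4 cells, and POU5F1, NANOG, SOX2 and TDGF1 lower ones.

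**Figure D1:**
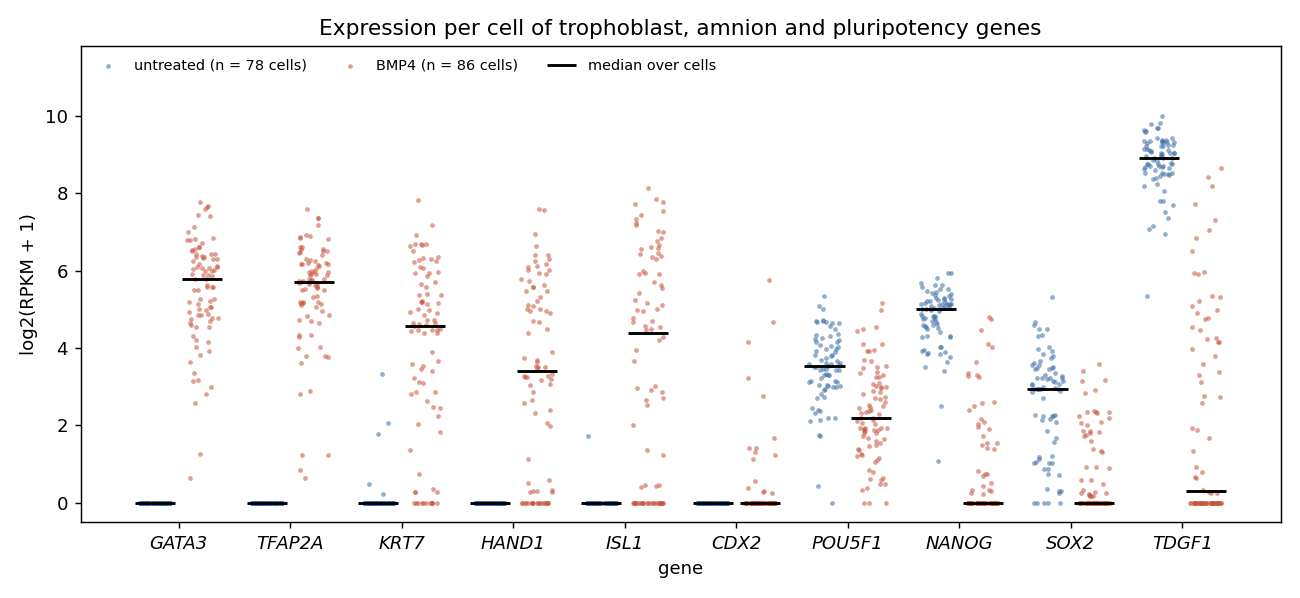
log2(RPKM + 1) per cell (vertical axis) of 10 genes (horizontal axis) in 78 untreated and 86 BMP4 cells. Each point is 1 cell and each black line a median over cells; untreated cells lie at 0 for GATA3, TFAP2A, HAND1 and CDX2, while POU5F1 values of the groups overlap (25th to 75th percentiles of 1.85 to 7.25 RPKM in BMP4 and 7.05 to 16.5 RPKM in untreated cells).

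Of 32 primitive streak and mesoderm genes, only 9 had deposited values and 5 were measured. Of the 5, 0 were at least 2-fold higher and 1 at least 2-fold lower (median -0.87, percentile 8.58). The receptor gene PDGFRA was listed at 0 in BMP4 cells and averaged 1.30 RPKM in untreated cells, and the retinoic acid hydroxylase gene CYP26A1 was at 8.47 against 3.85 RPKM. Higher and lower members were 4 and 4 after rescaling and 3 and 1 with size factors, and the median was 0.11 and 1.02, respectively. Of 7 measured endoderm genes, 3 were at least 2-fold higher and 2 at least 2-fold lower (median 0.75, percentile 98.5), or 5 and 2 after rescaling and 4 and 1 with size factors. The median was -0.15 (percentile 67.6) in the first of 2 sets of wells, and the percentile was 82.8 with trimmed means. The transthyretin gene TTR (14.2 against 0.0926 RPKM) was detected in 3 of 86 BMP4 cells, so a few cells decided its mean, which had a log2 ratio of -0.0299 as a trimmed mean. KIT, a receptor tyrosine kinase gene, was at 12.53 against 2.39 RPKM. APOA2 averaged 3.02 RPKM in BMP4 cells, where it was detected in 4 of 86, and was listed at 0 in untreated cells. AFP (1.08 against 4.23 RPKM) was lower, and CER1 was listed at 0 in BMP4 cells and averaged 1.20 RPKM in untreated cells. Of 6 measured neuroectoderm genes, 0 were at least 2-fold higher and 3 at least 2-fold lower (median -0.91, percentile 2.90), or 1 and 2 after rescaling and 0 and 2 with size factors. ZIC5 (0.878 against 6.13 RPKM), MAP2 (0.160 against 1.94 RPKM) and the N-cadherin gene CDH2 (4.19 against 11.01 RPKM) were lower.

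Of 8 measured genes of naive pluripotency, 5 were at least 2-fold higher in BMP4 cells and 2 at least 2-fold lower (median 1.32, percentile 99.98). TFAP2C (270.1 against 7.48 RPKM) is also in the early trophoblast list. TBX3 (15.02 against 0.00189 RPKM) is also in the BMP target list and in that of syncytiotrophoblast and extravillous trophoblast. The Kruppel-like factor gene KLF4 was at 5.68 against 0.572 RPKM, and DPPA5 was listed at 0 in BMP4 cells and averaged 2.18 RPKM in untreated cells. Of 7 measured retinoid, HOX and CDX patterning genes, 3 were at least 2-fold higher and 1 at least 2-fold lower (median 0.96, percentile 99.8), or 6 and 1 after rescaling and 4 and 0 with size factors. Its percentile was 94.7 with trimmed means, 87.3 at a minimum of 10 RPKM and 88.99 without members shared with other lists. MEIS1, a homeobox gene, averaged 27.2 RPKM in BMP4 cells and was listed at 0 in untreated cells, while the retinoic acid binding protein gene CRABP1 was at 32.2 against 77.6 RPKM.

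Of 20 measured epithelial adhesion and mesenchymal genes, 6 were at least 2-fold higher in BMP4 cells and 4 at least 2-fold lower (median 0.22, percentile 99.7), or 9 and 2 after rescaling and 9 and 1 with size factors. Beside FN1, the E-cadherin gene CDH1 (37.3 against 12.97 RPKM) and the claudin gene CLDN4 (32.2 against 3.79 RPKM) were higher, as was the mesenchymal transcription factor gene TWIST1 (8.47 against 0.0895 RPKM). CDH2 (4.19 against 11.01 RPKM) and the integrin gene ITGA6 (3.29 against 13.8 RPKM) were lower. Feeder and stromal fibroblast genes, included as markers of other cells a culture could hold, had 2 of 10 measured members at least 2-fold higher and 2 at least 2-fold lower (median 0.48, percentile 99.3), or 4 and 1 after rescaling and 4 and 1 with size factors. With a minimum mean of 10 RPKM the median was -0.63 (percentile 32.4). The collagen genes COL1A1 (7.53 against 5.74 RPKM) and COL1A2 (8.36 against 4.42 RPKM) were low in both groups. POSTN (20.9 against 0.298 RPKM), also in the amnion list, was the highest member and THY1 (3.54 against 48.2 RPKM), also in the pluripotency list, the lowest.

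DNA replication and S phase genes were lower in BMP4 cells: 13 of 24 measured members were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.08 (percentile 0). The replicative helicase genes MCM5 (6.90 against 34.9 RPKM) and MCM4 (35.6 against 138.01 RPKM) and the cyclin gene CCNE2 (1.93 against 14.3 RPKM) had the lowest ratios, and the thymidylate synthase gene TYMS (21.6 against 25.96 RPKM) the highest. With size factors, 7 members were at least 2-fold lower. Of 25 measured G2 and mitosis genes, 7 were at least 2-fold lower and 0 at least 2-fold higher (median -0.74, percentile 2.62), and 1 was at least 2-fold lower under either scaling. The mitotic kinase gene PLK1 (7.23 against 29.02 RPKM) had the lowest ratio, whereas MKI67 (8.18 against 8.52 RPKM) and TOP2A (36.3 against 39.6 RPKM), genes of cycling cells, lay within 2-fold. PLK1 was detected in 34.9% of BMP4 cells (24.9 to 45.9%) and 82.1% of untreated cells (71.7 to 89.8%).

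Of 18 measured glycolysis genes, 6 were at least 2-fold lower in BMP4 cells and 1 at least 2-fold higher (median -0.67, percentile 7.48). Higher and lower members were 2 and 6 after rescaling and 1 and 3 with size factors. The glucose transporter gene SLC2A3 was higher (513 against 119.5 RPKM), while the hexokinase gene HK1 (12.7 against 40.6 RPKM) and the lactate dehydrogenase gene LDHA (202 against 524 RPKM) were lower. Of 31 measured nuclear genes of oxidative phosphorylation, 26 lay within 2-fold, 1 was higher and 4 were lower (percentile 97.8). Their median of -0.20 turned to 0.12 after rescaling and 0.22 with size factors (percentiles 96.99 and 96.7), where 1 was higher and 1 lower. SDHC (4.24 against 1.049 RPKM) and the respiratory complex gene NDUFS3 (24.02 against 76.5 RPKM) lay at the ends. Of 49 cytosolic ribosomal protein genes, 47 lay within 2-fold, 0 were higher and 2 lower: RPL13 (69.5 against 193 RPKM) and RPL7 (18.7 against 46.3 RPKM). Their median of -0.24 (percentile 99.3) turned to 0.0886 and 0.118 (percentiles 98.7 and 92.8), and higher and lower members were 1 and 1 after rescaling and 1 and 0 with size factors. These genes have many pseudogenes, and their single values are uncertain.

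Of 22 measured immediate early and stress genes, 7 were at least 2-fold higher in BMP4 cells and 3 at least 2-fold lower (median 0.14, percentile 98.8), or 9 and 1 after rescaling and 8 and 1 with size factors, with percentiles of 97.8 and 94.8. The AP-1 genes FOS (70.002 against 11.2 RPKM) and JUND (31.5 against 6.74 RPKM) were higher, and the chaperone genes HSPA8 (372 against 883 RPKM) and DNAJB1 (5.08 against 11.3 RPKM) lower. With a minimum mean of 10 RPKM the median was -0.0975 (percentile 92.1). Of 18 measured p53 target and apoptosis genes, 6 were at least 2-fold higher and 3 at least 2-fold lower (median 0.50, percentile 99.9), or 8 and 1 after rescaling and 8 and 0 with size factors. The antiproliferative gene BTG2 (7.72 against 0.110 RPKM), the cyclin-dependent kinase inhibitor gene CDKN1A (8.91 against 0.851 RPKM) and MDM2 (148.7 against 41.7 RPKM), which encodes the ubiquitin ligase of p53, were higher. PMAIP1 (24.5 against 63.4 RPKM), a pro-apoptotic gene, was lower. With a minimum of 10 RPKM the median was -0.17 (percentile 75.01).

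Genes of DNA methylation and demethylation had 6 of 12 measured members at least 2-fold lower in BMP4 cells and 1 at least 2-fold higher (median -1.004, percentile 0.480), with 1 and 4 after rescaling and 1 and 2 with size factors higher and lower. The percentile was 4.06 and 2.77 in the 2 sets of wells and 5.42 without members shared with other lists. DNMT3A (65.3 against 175.2 RPKM) and DNMT3B (26.04 against 201 RPKM), the de novo methyltransferases, and the corepressor gene TRIM28 (6.85 against 22.2 RPKM) were lower, and the demethylation enzyme gene TET2 (8.13 against 0.448 RPKM) was higher. Of 18 measured polycomb and trithorax genes, 6 were at least 2-fold lower and 0 at least 2-fold higher (median -0.44, percentile 21.1), or 3 and 4 after rescaling and 2 and 3 with size factors for higher and lower. PHC1 (6.79 against 35.96 RPKM) and WDR5 (0.878 against 7.82 RPKM) had the lowest ratios and the H3K4 demethylase gene KDM5B (22.05 against 11.9 RPKM) the highest. Of 16 measured imprinted genes, 1 was at least 2-fold higher and 6 at least 2-fold lower (median -0.27, percentile 63.3), or 5 and 2 after rescaling and 2 and 1 with size factors, with medians of 0.43 and 0.14. The cyclin-dependent kinase inhibitor gene CDKN1C (17.1 against 2.32 RPKM) was the higher member, and MEST (46.9 against 116.3 RPKM) and NNAT (6.70 against 19.9 RPKM) were the lowest. SNRPN (395 against 885 RPKM) and SNURF (493 against 1083 RPKM) overlap and share reads.

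Of 19 measured MHC class I and interferon response genes, 2 were at least 2-fold higher in BMP4 cells and 5 at least 2-fold lower (median -0.46, percentile 22.1), or 4 and 6 after rescaling and 4 and 4 with size factors. The interferon-induced membrane protein genes IFITM2 (29.5 against 369.9 RPKM) and IFITM1 (149.1 against 584 RPKM), near-identical copies whose single values are uncertain, were lower, and B2M (192.2 against 87.7 RPKM), the light chain of MHC class I, and IFI6 (9.41 against 1.91 RPKM) were higher. Of 12 measured Wnt signalling genes, 1 was at least 2-fold higher and 5 at least 2-fold lower (median -0.70, percentile 7.22), or 5 and 6 after rescaling and 3 and 4 with size factors, with percentiles of 24.5 and 0.430. The secreted Wnt modulator genes SFRP1 (2.59 against 39.3 RPKM) and SFRP2 (4.05 against 81.1 RPKM) were lower, and the transcription factor gene TCF7L2 (55.7 against 25.5 RPKM) was the higher member.

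**Figure D2:**
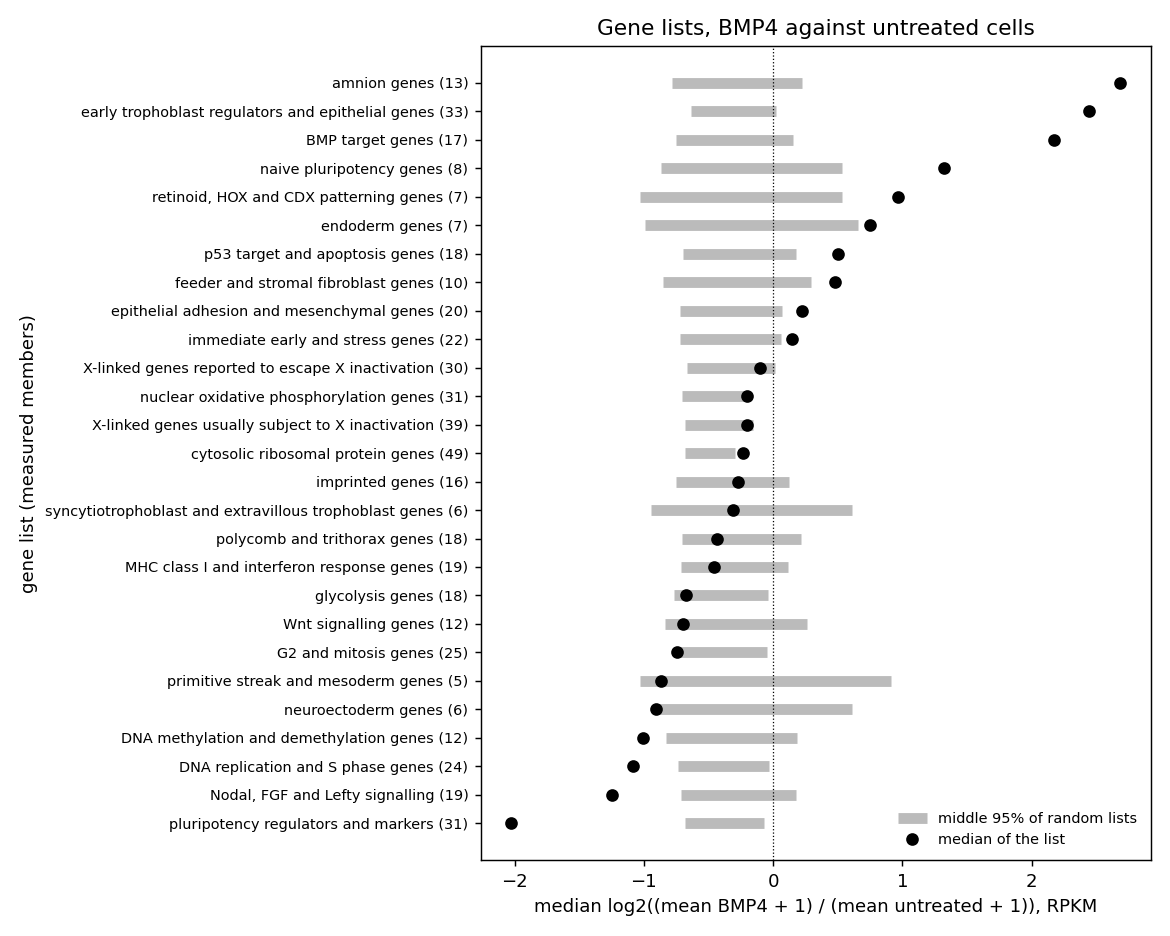
Median log2 ratio of BMP4 to untreated cells (horizontal axis) for each gene list (vertical axis, with the number of measured members). Points are list medians and grey bars the middle 95% of 10000 random lists matched on size and expression; amnion (2.68), trophoblast (2.45) and BMP target genes (2.18) lie above their bars, and pluripotency genes (-2.02) below.

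X-linked genes were compared with autosomal genes. Among genes with a mean RPKM of 5 or more, 244 X-linked genes had a median log2 ratio of -0.25 and 7021 autosomal genes one of -0.38, a difference of 0.13 (percentile 99.3 of matched autosomal lists). SAT1, which encodes a polyamine acetyltransferase, had the largest ratio of the X-linked lists (796 against 47.7 RPKM), and the clathrin adaptor gene AP1S2 (3.84 against 29.6 RPKM) the smallest. Of 30 measured genes reported to escape X inactivation, 5 were at least 2-fold higher and 3 at least 2-fold lower (median -0.0999, percentile 92.6), or 6 and 2 after rescaling and 8 and 2 with size factors; the steroid sulfatase gene STS was at 5.66 against 0.129 RPKM. Of 39 measured genes usually subject to it, 3 were at least 2-fold higher and 4 at least 2-fold lower (median -0.21, percentile 94.2), or 5 and 1 after rescaling and 6 and 1 with size factors, with HPRT1 at 40.7 against 97.2 RPKM. Both medians were above 0 under either scaling: 0.16 and 0.32 for escaping genes, 0.15 and 0.26 for the others.

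Per cell, the median RPKM of the X-linked genes over that of autosomal genes had a median of 0.747 in BMP4 cells (25th to 75th percentile 0.450 to 0.926) and 0.809 in untreated cells (0.651 to 0.940), over the 85 and 77 cells in which the autosomal median was above 0. The ratio of the means went the other way, 1.03 against 0.805, and without SAT1 it was 0.969 against 0.808. No direction per cell was therefore read from these ratios.

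Whether pluripotency and trophoblast genes were found in the same cells was addressed by co-detection at an RPKM of 1 or more. POU5F1 and GATA3 were both detected in 74 of 86 BMP4 cells (86.05%, 95% interval 76.9 to 92.6%). NANOG and GATA3 were both detected in 24 of 86 BMP4 cells (27.9%, 95% interval 18.8 to 38.6%), and SOX2 and GATA3 in 25 of 86 BMP4 cells (29.1%, 95% interval 19.8 to 39.9%). GATA3 was detected in 85 of 86 BMP4 cells, so its pairs follow the share of the other gene and tell nothing of association. KRT7 was detected in 14 of 26 (53.8%, 95% interval 33.4 to 73.4%) BMP4 cells with SOX2 and 56 of 60 (93.3%, 95% interval 83.8 to 98.2%) without, and in 15 of 25 (60%, 95% interval 38.7 to 78.9%) with NANOG and 55 of 61 (90.2%, 95% interval 79.8 to 96.3%) without. BMP4 cells with SOX2 had a median of 7379 genes and those without 6436 (NANOG, 7236 and 6463). HAND1 was detected in 15 of 26 cells with SOX2 and 45 of 60 without, and in 17 of 25 with NANOG and 43 of 61 without, with overlapping intervals. CDX2 was detected in 1 of 26 and 10 of 60 for SOX2, and in 3 of 25 and 8 of 61 for NANOG. POU5F1 was found with HAND1 in 51 cells, with KRT7 in 59 and with CDX2 in 9, and only 12 BMP4 cells were without it. In untreated cells, POU5F1, NANOG or SOX2 were found with GATA3, HAND1 or CDX2 in 0 of 78 cells, which allows up to 3.85%, and with KRT7 in 3. The POU5F1 and GATA3 share was 37.2% at an RPKM of 5 or more and 96.5% at any value above 0.

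The first principal component of the 1000 most variable genes held 17.1% of the variance (component 2, 3.77%). On it, the 25th to 75th percentiles were -43.05 to -20.2 for BMP4 cells and 30.3 to 36.9 for untreated cells, while the full ranges overlapped (-53.4 to 15.2 and -22.1 to 48.8). The untreated cells with the lowest values, at -22.1 and 12.3, had 2709 and 5462 genes. Of the 4 clusters, cluster 1 held 76 untreated cells, cluster 2 held 30 BMP4 cells, cluster 3 held 32 BMP4 cells, and cluster 4 held 24 BMP4 cells and 2 untreated cells. These 2 were the untreated cells with 2709 and 5462 genes. Cells in a cluster led by the other group numbered 0 with 6 clusters, 0 with 500 variable genes, 1 with 3000 and 0 without the cell filter. The median number of genes per cell was 7742, 7668, 6772 and 5529.5 in clusters 1 to 4. With each group taken as 1 chip, the separation of untreated from BMP4 cells can be the chip. This does not cover the split among BMP4 cells, which share 1 run and 1 inferred chip, and the cause of that split was not tested. Clusters were given no cell type name.

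**Figure D3:**
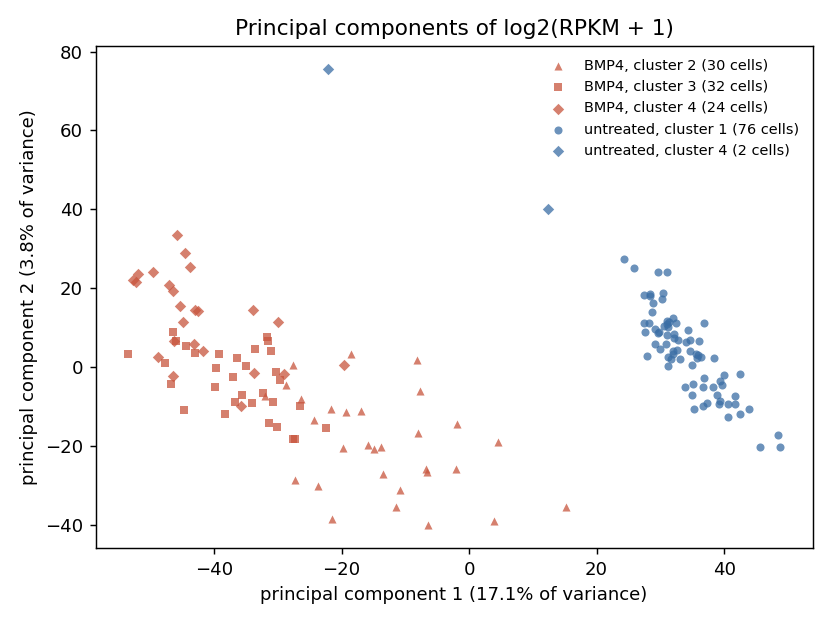
First (horizontal axis) and the second principal component (vertical axis) of log2(RPKM + 1), with each point 1 cell, coloured by group and shaped by cluster. BMP4 cells form 3 clusters of 30, 32 and 24 cells, and 2 untreated cells, with 2709 and 5462 genes, fall in the last of these. With 6 clusters or 500 variable genes, 0 cells fell in a cluster led by the other group.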

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

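Thinned shares, lists without shared members and X-linked genes without SAT1 were chosen after seeing the data. No paired analysis was possible because the groups are single samples whose cell numbers are not shared. Rescaling without mitochondrially encoded genes was not run, since none is in the tables. Of 1270 log2 ratios of named genes under 10 alternatives, 253 moved by over 1.5-fold and 2 changed sign (a ratio of exactly 0, as for PDGFRA, counted as moved, a choice made after seeing the data): TTR, at -0.0299 as a 10% trimmed mean and -0.0805 in the first set of wells, a gene detected in 3 BMP4 cells. The medians of the pluripotency, Nodal, BMP target, trophoblast, amnion, S phase and epithelial lists stayed in the outer 2.5% of random lists on the same side in all 13 settings and that of the naive list in all 12 run. Other lists kept that place in fewer: endoderm in 8 of 13, oxidative phosphorylation in 6, ribosomal in 11, stress in 9, fibroblast in 9, p53 in 12, DNA methylation in 10 and retinoid in 10.

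The median of measured genes was -0.17 with a pseudocount of 5, -0.00301 after rescaling and 0.11 with size factors. A pseudocount of 0.1 gave medians of 4.35 for BMP targets, 3.67 for trophoblast and 3.33 for amnion genes, and one of 5 gave 1.46, 1.56 and 1.51, and -1.22 for pluripotency genes, as a larger pseudocount shrinks ratios of low genes. Rescaling gave 3.41 for BMP targets and 3.23 for trophoblast genes, and turned oxidative phosphorylation to 0.12 and ribosomal genes to 0.0886; size factors turned these to 0.22 and 0.118 and left 7 S phase genes at least 2-fold lower. The mean of logs gave 1.59 for trophoblast and 1.85 for amnion genes. The 2 sets of wells gave 2.84 and 2.82 for BMP targets, and the first gave -0.15 for endoderm genes. Without a minimum, amnion genes had 2.09 and stress genes -0.00242. At 10 RPKM or more, fewer members remained: Nodal -2.10 with 6 lower, BMP targets 3.97, trophoblast 4.13, amnion 3.61, fibroblast -0.63, stress -0.0975 and p53 genes -0.17. X-linked minus autosomal was 0.33 at 20 RPKM or more and 0.0764 (percentile 95.6) at 1 RPKM or more. POU5F1 and GATA3 were co-detected in 96.5% of BMP4 cells above 0 and 37.2% at 5 or more. Cells in a cluster led by the other group numbered 0 with 6 clusters, 0 with 500 variable genes, 1 with 3000 and 0 without the cell filter. Where no construction is named, the cause was not tested.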

Other observations

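These families were chosen after their values were seen, as were the test on RPKM scaling, the count in the capture test and its median without widely detected genes; that the intervals of the gene length and capture tests should count was also decided after their values were seen. All 6 measured metallothionein genes, which encode metal-binding proteins, were at least 2-fold lower in BMP4 cells, with a median log2 ratio of -2.76 (-2.76 after rescaling, -2.37 with size factors): MT1X (10.7 against 255 RPKM), MT1H (0.0595 against 14.3 RPKM), MT1G (3.04 against 53.8 RPKM), MT1F (2.93 against 12.4 RPKM), MT2A (4.02 against 14.7 RPKM) and MT1E (0.820 against 3.41 RPKM). Of 43 measured replication-dependent histone genes, 16 were at least 2-fold lower and 1 at least 2-fold higher (median -0.89, -0.93 and -0.62), among them the linker histone gene HIST1H1B (12.96 against 119.9 RPKM). Both families hold near-identical copies, so single values are uncertain. How fully the cDNA step captured replication-dependent histone transcripts was not tested, so their lower values are not read as lower transcript amounts. Of 9 measured annexin genes, which encode calcium-dependent membrane-binding proteins, 5 were at least 2-fold higher and 0 lower (median 1.95, 2.28 and 2.39), such as ANXA3 (298 against 76.2 RPKM) and ANXA2 (249.8 against 47.96 RPKM). Of 8 S100A genes, 5 were higher, such as S100A11 (461 against 128.9 RPKM), and 1 lower (median 1.35, 1.90 and 1.45).

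Amnion and trophoblast genes were compared within BMP4 cells, in pairs also chosen after the values were seen. HAND1 was detected in 48 of 57 (84.2%, 95% interval 72.1 to 92.5%) BMP4 cells with ISL1 and 12 of 29 (41.4%, 95% interval 23.5 to 61.1%) without. NANOG was detected in 11 of 57 (19.3%, 95% interval 10.05 to 31.9%) with ISL1 and 14 of 29 (48.3%, 95% interval 29.4 to 67.5%) without, the intervals just overlapping. The median number of genes was 6463 in cells with ISL1 and 6968 in those without. For VGLL1 the shares were 21 of 57 (36.8%, 95% interval 24.4 to 50.7%) with ISL1 and 8 of 29 (27.6%, 95% interval 12.7 to 47.2%) without, and 12 of 33 (36.4%, 95% interval 20.4 to 54.9%) with GABRP and 17 of 53 (32.1%, 95% interval 19.9 to 46.3%) without. Cells are not replicates, and these intervals cover counting error only.

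Most measured genes were lower in BMP4 cells, with a median log2 ratio of -0.31. A gene length bias between the chips was argued against: the 25% longest and the 25% shortest genes differed by 0.0773 (95% interval over resampled genes 0.0327 to 0.125), where a bias would give 0.3 or more, a size that the interval excludes although it passes the bound of 0.1 set beforehand for no bias. Rescaling each cell to the same sum moved the median by 0.31 to -0.00301, but the group sums alone set a shift of 0.35, so this decides nothing about RPKM scaling as an explanation. Scaling, the chip and a biological difference after BMP4 cannot be told apart, since run and group coincide, as does the chip if each group filled 1, and the lower sums have no replicate.

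Ribosomal protein genes differed widely within untreated cells, from 10.5 to 3251 RPKM. Reads shared with processed pseudogenes, if not counted, may be part of this: across 49 genes, the number of pseudogene copies and the mean RPKM had a Spearman rho of -0.319, just past the bound of -0.3 set beforehand, over genes that are not independent replicates. The median was 513 RPKM for genes with fewer copies and 299.8 for those with more. Both ends of the range were genes with fewer copies, RPS28 (10.5 RPKM, 3 copies) and RPL23 (3251 RPKM, 5 copies), so the number of copies does not account for the range. How the reads were counted is not given in the sources used here, and no biological explanation was tested.

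Several of the 14 genes of the early trophoblast and amnion lists at 10 RPKM or more in BMP4 cells and found in under 5% of untreated cells, such as VGLL1 (33.7%), GABRP (38.4%) and ISL1 (66.3%), were detected in part of the BMP4 cells only. By detected share among the 200 genes closest in mean RPKM, 8 of the 14 lay below the 10th percentile (57.1%, exact 95% interval 28.9 to 82.3%, treating genes as independent, although some were detected in the same cells), with VGLL1 at 3, GABRP at 2.5 and ISL1 at 2.75; loss of transcripts at capture as for any gene of that level would put 10% there, so it was argued against as the whole explanation. The median percentile was 6.625, below the bound of 10 set beforehand, but its interval of 2.75 to 74.2 reached up to genes found in nearly all BMP4 cells, TFAP2A (74.2), GATA3 (79) and MSX2 (89.2); without these it was 3.5 (2.5 to 40.2), though leaving out widely detected genes lowers it by construction. With the later trophoblast list, chosen after the values were seen, TBX3 (83.8) was added, the share was 53.3% (26.6 to 78.7%) and the median 7.75. By detected share, loss at capture stays open for HAND1 (29), KRT7 (40.2) and GRHL3 (54). HAND1 was in 84.2% of BMP4 cells with ISL1 and 41.4% without, and KRT7 in 53.8% with SOX2 and 93.3% without. Loss unrelated to other genes would not give such gaps, and the higher shares lay in cells with fewer genes. These shares were added after the data were seen, and HAND1 with SOX2 or NANOG had overlapping intervals, so they do not decide. Differences between cells stay open for all 14 genes and were otherwise not tested.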
